A study of Homo sapiens with 6 samples.

How the data were processed

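RNA of 6 cultures of BJ-hTERT fibroblasts was measured on Illumina bead arrays, 1 array per culture. BJ-hTERT is an established line of foreskin fibroblasts immortalised with the catalytic subunit of telomerase. Per the labels' protocols, the cells were kept in medium with 1% serum, then left unstimulated or given PDGF-BB, a dimeric growth factor for mesenchymal cells, at 20 ng/mL for 24 h, with 3 cultures of each kind. Total RNA was amplified and labelled with biotin, per the labels' protocols. BeadStudio 3.1.3.0 is named in the submitters' processing notes, and no other processing step is given in the sources used here.

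The main file deposited by the authors holds, per the file headers, a linear signal intensity and a detection p-value for each probe on each array. The values differ in distribution between arrays and undetected probes lie near a signal of 31 on every array, so no normalization and no background subtraction is visible in them. The detection p-values deposited by the authors move in equal small steps and were given against negative control beads. A second table deposited by the authors holds normalized intensity values of the same arrays, on a linear scale and with no background subtracted. They are read here as quantile-normalized over all 6 arrays. Each column keeps the rank order of its own raw array (Spearman's rho 1), and the medians lie between 33.13 and 33.17. Other scalings of each array could give this too, so these checks do not single out quantile normalization. The columns of the second table carry sample names and need no direction, and centring was not found. No column belonged to a sample outside the series.

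For the analysis done here, the signals were background-corrected with limma's neqc, in which the normal-exponential background is inferred from the detection p-values and an offset of 16 is added, then quantile-normalized and taken to log2. Probes with a detection p under 0.05 on at least 3 arrays were kept. PDGF-BB and unstimulated arrays were compared with limma (version 3.58.1, R 4.3.3), using lmFit and eBayes with the group as the only term, 2-sided, with Benjamini-Hochberg adjustment over all kept probes and a threshold of 0.05. A fold change is on the scale of log2 of the background-corrected signal with its offset, so it understates the change of dim probes. Where a probe was not above background on any array of a group, a lower bound was computed against the lowest signal of the probes detected on those arrays. The number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

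Probes were named from the platform annotation table: 28098 probes had 1 gene symbol, 13 had several and 20692 were not listed there, so they are unnamed here. Symbols were checked through their gene identifiers against the RefSeq gene table, which changed none; 39 probes had no match and kept their symbol. A gene was represented by its kept probe with the highest mean over the arrays of the fit. No genome build is given in the sources used here, so no coordinates are printed.

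The design, the alternatives, the naming rule and 30 gene lists (563 genes, from textbook knowledge of fibroblasts, growth factor responses and other cell types) were fixed before the data were examined. Lists with at least 5 measured genes were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. The genes named were the 10 with the largest rise and the 10 with the largest fall among those past the threshold whose stimulated arrays all lay on one side of the unstimulated ones, leaving out symbols without a described product; up to 4 members of each list with the largest change past the threshold, or the single member with the largest change where none passed; the receptors PDGFRA and PDGFRB; and the most abundant measured gene of each marker list. Genes of a list named beyond that rule were chosen after their values were seen.

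The fixed design used all 6 arrays. Because the array of unstimulated replicate 1 had almost no signal, most results are given from the fit without it, which was 1 of the alternatives fixed beforehand, and the naming rule was applied to that fit. Using it as the basis of the account, and combining it with the other alternatives, was decided after the signals of that array were seen. The filter of 3 detected arrays was kept for 5 arrays. A gene detected only on the 3 stimulated arrays could pass it, and one detected only on the 2 remaining unstimulated arrays could not. Genes that fell below detection on every stimulated array were therefore not tested. The alternatives were other background corrections (normal-exponential with an offset of 50, or none), median scaling, cyclic loess, the deposited normalized values, other detection filters, the replicate number as a block, eBayes with trend and robust settings, array quality weights, the mean of a gene's probes, and leaving out each array.

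The scripts were tested on simulated data with 200 changed probes. For the comparison without the dim array (16840 probes), 84% of the probes changed by 1.5-fold and 100% of those changed by 2-fold were recovered, and 22 of 214 calls were false, which is above the nominal share. For the comparison with all 6 arrays (17033 probes), in which the simulated dim array carried its observed deviations, shuffled over the probes, 0% of the changes of 2-fold and of 4-fold were recovered. A simulated list shifted by a log2 value of 0.3 was called in each comparison, and of 20 unshifted lists 0 were called without the dim array and 1 with it. Genes of the report that were left out of a refit by the detection filter are not counted as lost there.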

Results

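Gene expression was measured in BJ-hTERT fibroblasts after 24 h with or without PDGF-BB at 20 ng/mL, in 3 cultures each, to obtain the genes that respond to this growth factor. On 5 of the 6 arrays between 17003 and 17845 probes were detected, and the 99th percentile of the signal lay between 2719 and 3261. The array of unstimulated replicate 1 detected 8533 probes, and its 99th percentile was 64.0 while its median, 31.4, was close to that of the other arrays (33.3 to 33.8). Of the 12119 probes detected at a p under 0.01 on each of the other 5 arrays, 32.5% were detected on this one. Its signals correlated with those of the other arrays at Spearman's rho of 0.235 to 0.248 across probes, compared with 0.817 to 0.828 among the other 5. It is called the dim array here. In the authors' normalized values its median, 33.13, stood beside 33.16 to 33.17 on the others.

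**Figure D1:**
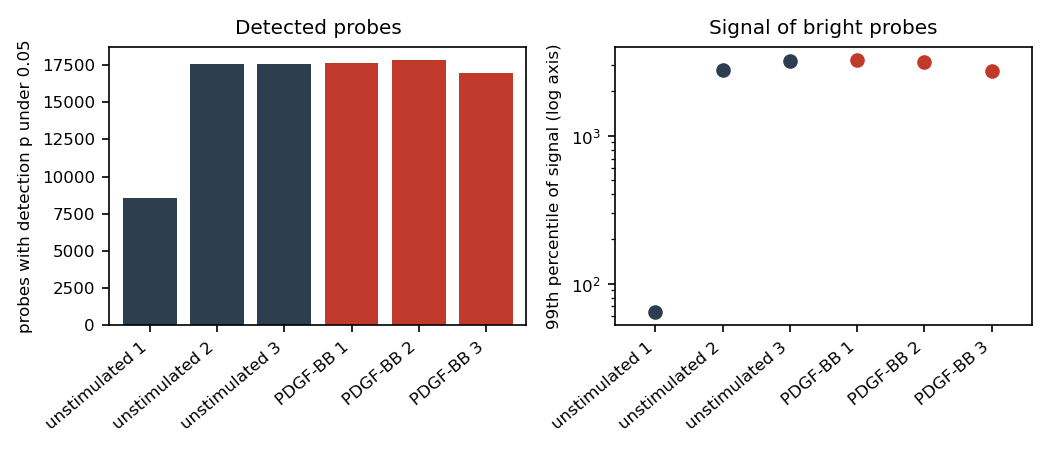
Number of probes with a detection p under 0.05 (left, bars from 0) and 99th percentile of the raw signal (right, log axis) for each of the 3 unstimulated arrays (dark) and 3 PDGF-BB arrays (red). Unstimulated replicate 1 has 8533 detected probes and a 99th percentile of 64.0, and the other 5 arrays have at least 17003 and at least 2719.

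In the fit fixed beforehand, with all 6 arrays, PDGF-BB changed no gene past the threshold: 0 of 10510 genes had an adjusted p under 0.05 in limma, the lowest adjusted p was 0.519, and 192 genes had an unadjusted p under 0.05 where chance alone gives 525.5. The median fold change over all genes was 0.40 on the log2 scale. The largest member changes of the 30 gene lists in that fit ranged from 0.25 to 2.83 in absolute log2 value, with standard errors from 0.20 to 1.40; the largest was that of STC1. Without the dim array (3 stimulated and 2 unstimulated arrays) the median fold change was 0.00. In that fit 258 genes were higher and 475 lower in stimulated cells, 7.0% of the 10464 tested, and 33 rose and 41 fell by at least 2-fold. At the level of probes 442 were higher and 632 lower. When unstimulated replicate 2 or 3 was left out as well, 1 unstimulated array remained and fewer genes passed. Such a refit has no spread among unstimulated arrays, so a call lost there may reflect lower precision and not a changed value. Over the refits without 1 more array, PDGFRA ranged from 0.58 to 0.64 and DUSP6 from 0.63 to 1.07. A fit that kept all 6 arrays and weighted each by its quality gave the dim array a weight of 0.0104 against 2.19 to 2.95 for the others. It called 417 genes higher and 652 lower, among them 732 of the 733 called without the dim array. At that weight the dim array adds almost nothing, so the overlap was nearly fixed beforehand and is not separate support. The weighted fit still counted it as an array, with 4 residual degrees of freedom against 3. Of those 733 genes, 540 had the same sign in the unweighted fit of 6 arrays. The values that follow are from the 5 arrays unless stated otherwise. Values of single genes are log2 fold changes ± SE with n = 3 and 2, and no gene named below passed the threshold in the unweighted fit of 6 arrays. Of the 85 genes named by the fixed rule that passed without the dim array, 76 had the same sign in that fit. The other 9, all lower without the dim array, had positive values there: ADAMTS1 (0.66), CCNG2 (0.51), KCNJ8 (0.48), C1S (0.46), ID2 (0.32), PDGFRB (0.27), MX1 (0.15), CNN1 (0.12) and EFEMP1 (0.01).

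IL13RA2, a decoy receptor for interleukin 13, rose by 2.64 ± 0.14 (6.25-fold, adjusted p = 1.88e-05), and STC1, which encodes the secreted glycoprotein stanniocalcin 1, rose by 2.28 ± 0.13 (4.85-fold). TMEM158, a membrane protein induced by Ras signalling, rose by 1.89 ± 0.11, the vesicle protein gene SYT7 by 1.88 ± 0.14, the proteoglycan gene ESM1 by 1.83 ± 0.11 and the acid phosphatase gene ACP3 by 1.82 ± 0.13. MMP1, the interstitial collagenase, rose by 1.77 ± 0.11 (3.40-fold), HAS2, a hyaluronan synthase, by 1.72 ± 0.14 and the trypsinogen gene PRSS3 by 1.72 ± 0.12. The neurotensin receptor gene NTSR1 was not above background on either unstimulated array and was at least 3.31-fold higher after stimulation. IL13RA2 was detected on 1 of the 2 unstimulated arrays, and of the 3 other probes of SYT7 only 1 had the same sign.

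Among the genes that fell, OLFM4, a secreted olfactomedin glycoprotein, was 5.35-fold lower (-2.42 ± 0.11, adjusted p = 1.14e-05), followed by the carboxypeptidase gene CPA4 (-2.22 ± 0.13). The netrin gene NTN4 fell (-1.92 ± 0.12), the receptor kinase gene ERBB3 (-1.91 ± 0.20) and SYPL2 (-1.76 ± 0.11). CCL2, the monocyte-attracting chemokine, fell (-1.58 ± 0.14), 3.00-fold lower, and the adhesion molecule gene CADM1 (-1.54 ± 0.12). BAMBI, a pseudoreceptor that dampens TGF-beta signalling, fell (-1.53 ± 0.18), PLPPR4 (-1.52 ± 0.14) and RCAN2, a regulator of calcineurin, (-1.48 ± 0.12). CPA4 and SYPL2 were detected on 1 of 3 stimulated arrays and PLPPR4 on 2 of 3. In each of these 20 genes the stimulated arrays all lay on one side of the unstimulated ones, which the naming rule required. Each kept its call in every refit without 1 more array that tested it. CPA4, SYPL2 and NTSR1 passed the detection filter in 2 of those 5 refits, the other 17 genes in all 5.

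**Figure D2:**
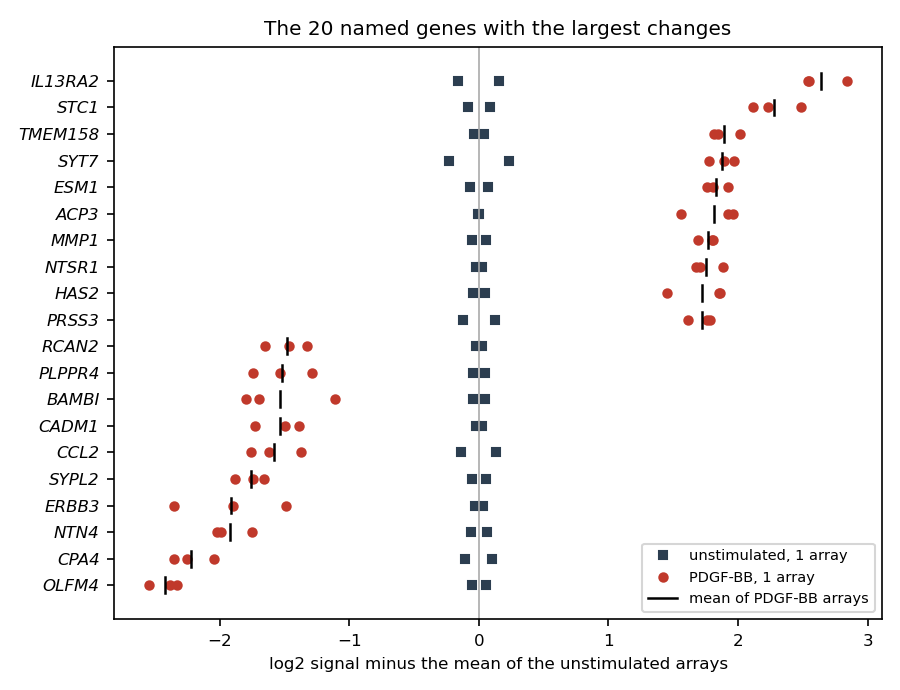
Log2 signal of the 10 genes with the largest rise and the 10 with the largest fall, minus the mean of the 2 unstimulated arrays (squares); each circle is 1 of the 3 PDGF-BB arrays, the short line is their mean, and the dim array is left out. IL13RA2 lies 2.64 above the unstimulated mean and OLFM4 lies at -2.42.

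Some immediate early genes and feedback regulators of MAPK signalling changed 24 h after stimulation, more of them upward than downward. Of 23 measured genes of the list of immediate early genes and MAPK feedback regulators, 8 rose, 2 fell and 13 did not pass the test (13 rose and 2 fell when adjusted over the list alone). PHLDA1 rose by 1.48 ± 0.12, the Sprouty genes SPRY4 and SPRY2, inhibitors of receptor tyrosine kinase signalling, by 1.29 ± 0.16 and 0.99 ± 0.10, and the ERK phosphatase gene DUSP6 by 0.85 ± 0.14. DUSP1 and SPRY1, chosen after their values were seen because they were the 2 that fell, dropped (-0.53 ± 0.11 and -0.47 ± 0.11). The immediate early gene FOS, also chosen afterwards, had a log2 fold change of 0.10 ± 0.12 (adjusted p = 0.680). The list was higher as a set in camera (adjusted p = 2.68e-06, and adjusted p = 0.0900 with an estimated correlation). The correlation estimated there was -0.0165, below the preset 0.01, so correlation between the genes does not account for the higher p. With all 6 arrays unweighted the list was also higher (adjusted p = 0.0287, and adjusted p = 0.988 with an estimated correlation). Of 5 measured PDGF ligands and receptors, the alpha receptor gene PDGFRA rose by 0.61 ± 0.10, while the beta receptor gene PDGFRB fell (-0.57 ± 0.13) and the receptor-like gene PDGFRL (-0.63 ± 0.11) (1 rose and 2 fell adjusted over the list alone). That list did not shift as a set (camera adjusted p = 0.361). In the unweighted fit of 6 arrays the PDGFRB value was 0.27 ± 0.74. DUSP6 and PDGFRL lost their calls when unstimulated replicate 2 was also left out (adjusted p = 0.0612 and 0.0944). PDGFRA lost its call when either remaining unstimulated array was left out (adjusted p up to 0.0622), and PDGFRB in those refits and without PDGF-BB replicate 1 or 2 (adjusted p up to 0.139).

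Growth factor and cytokine genes changed in each direction. Of 16 measured growth factor genes 5 rose and 3 fell (7 and 4 adjusted over the list alone). Besides STC1, the hepatocyte growth factor gene HGF rose by 1.39 ± 0.16, ANGPTL4 by 0.89 ± 0.13 and EREG, a ligand of the EGF receptor, by 0.83 ± 0.12. The set was higher in camera (adjusted p = 0.0357, and adjusted p = 0.178 with an estimated correlation). It did not pass with all 6 arrays (adjusted p = 0.0517), nor without the dim array when no detection filter or the stricter one was used. Of 10 measured cytokine and chemokine genes 3 rose and 3 fell (3 and 4 adjusted over the list alone): besides CCL2, the interleukin gene IL6 fell (-0.80 ± 0.12), whereas the neutrophil chemokine gene CXCL8 rose by 0.78 ± 0.10 and the prostaglandin synthase gene PTGS2 by 1.07 ± 0.12. The cytokine list did not shift as a set (camera adjusted p = 0.816).

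Many collagen genes and some genes of other matrix glycoproteins fell. Of 24 measured genes for collagens and collagen-modifying enzymes, 0 rose, 12 fell and 12 did not pass (19 fell adjusted over the list alone), with a median log2 fold change of -0.42. COL3A1 fell (-1.19 ± 0.12), 2.28-fold lower, COL4A1 (-1.18 ± 0.10), COL5A2 (-1.09 ± 0.12) and COL15A1 (-0.98 ± 0.13). COL1A1 and COL1A2, which encode the chains of type I collagen, fell (-0.92 ± 0.11 and -0.59 ± 0.12). The camera test gave an adjusted p of 9.65e-13, and adjusted p = 0.0900 with an estimated correlation. Of 19 measured elastic fibre and matrix glycoprotein genes 9 fell and 1 rose (13 and 2 adjusted over the list alone). EFEMP1 fell (-1.21 ± 0.13), the small proteoglycan genes LUM and DCN (-0.96 ± 0.11 and -0.84 ± 0.11), and SPARC (-0.91 ± 0.12). The gene that rose was TNC (0.50 ± 0.11), which encodes tenascin C and was chosen after its value was seen. That set was lower in camera (adjusted p = 2.68e-06, and adjusted p = 0.0900 with an estimated correlation). The collagen and the matrix glycoprotein lists were also lower with all 6 arrays unweighted (camera adjusted p = 2.87e-11 and 0.00482, and adjusted p = 0.0759 and 0.988 with an estimated correlation), although the median of the glycoprotein list was then 0.07, since camera compares a list with the other genes. Under median scaling of all 6 arrays in place of quantile normalization neither list passed and the direction of each turned, with a collagen median of 0.35. COL1A2 lost its call when either remaining unstimulated array was left out, and without PDGF-BB replicate 2 (adjusted p up to 0.109).

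Contractile genes fell in part, and matrix proteases changed in each direction. Of 15 measured contractile and myofibroblast genes 6 fell and 1 rose (10 and 1 adjusted over the list alone). The calponin gene CNN1 fell (-0.93 ± 0.12), TPM1 (-0.71 ± 0.11), the myosin light chain gene MYL9 (-0.68 ± 0.13) and CALD1 (-0.61 ± 0.12). The gene that rose was SMTN, with 0.56 ± 0.11. The smooth muscle actin gene ACTA2 had a value of -0.31 ± 0.11 (adjusted p = 0.131); it and SMTN were chosen after their values were seen. The set was lower in camera (adjusted p = 5.99e-06, and adjusted p = 0.0900 with an estimated correlation), also with all 6 arrays unweighted (adjusted p = 0.00013, and adjusted p = 0.307 with an estimated correlation), but not with all 6 arrays and median scaling, where its direction turned. In the unweighted fit of 6 arrays its median was -0.08, with 6 of 15 values positive, so much of that shift was relative to the other genes. Of 3 other TPM1 probes 2 had the same sign. Of 16 measured genes for matrix proteases and their inhibitors, 5 rose and 3 fell (7 and 4 adjusted over the list alone). With MMP1 rose the stromelysin gene MMP3 (0.92 ± 0.12) and the urokinase gene PLAU (0.67 ± 0.12), while ADAMTS1 fell (-0.73 ± 0.12). Of 7 measured hyaluronan-related genes, HAS2 and the versican gene VCAN (0.66 ± 0.15) rose, and the hyaluronan receptor gene LAYN fell (-1.02 ± 0.11); these calls were the same adjusted over the list alone. Neither the protease nor the hyaluronan list shifted as a set in camera (adjusted p = 0.278 and 0.251), but fry called each higher (adjusted p = 0.00546 and 0.0279). When either remaining unstimulated array was left out, CALD1, ADAMTS1, PLAU and VCAN lost their calls, VCAN also without PDGF-BB replicate 2 or 3, and MYL9 lost its call without unstimulated replicate 3 (adjusted p up to 0.157).

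Some targets of TGF-beta and BMP signalling and some genes of the IGF axis fell. Of 15 measured TGF-beta and BMP targets 7 fell and 1 rose (8 and 2 adjusted over the list alone). Besides BAMBI, the connective tissue growth factor gene CCN2 fell (-1.22 ± 0.10), 2.33-fold lower, and the inhibitor-of-differentiation genes ID3 and ID2 (-1.14 ± 0.14 and -1.10 ± 0.10). The gene that rose, named after its value was seen, was BMP2 (0.84 ± 0.10), itself a ligand of the pathway and detected on 1 of the 2 unstimulated arrays. The set was lower in camera (adjusted p = 0.000789, and adjusted p = 0.0981 with an estimated correlation). All 10 measured genes of the IGF and insulin axis had negative values, of which 5 passed (10 adjusted over the list alone). PAPPA, a protease of IGF-binding proteins, fell (-0.77 ± 0.11), the binding protein gene IGFBP5 (-0.76 ± 0.11), STC2 (-0.68 ± 0.11) and IGFBP4 (-0.67 ± 0.11). That set was lower (adjusted p = 1.94e-07, and adjusted p = 0.0981 with an estimated correlation). With all 6 arrays unweighted the 2 sets were also lower (camera adjusted p = 0.00187 and 2.91e-09, and adjusted p = 0.266 and 0.0698 with an estimated correlation), and neither passed there with median scaling. The TGF-beta and BMP list was lower there only relative to the other genes, with a median of 0.05 and 8 of 15 values positive. STC2 and IGFBP4 lost their calls when unstimulated replicate 2 was also left out (adjusted p up to 0.0834).

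Some genes of quiescence fell, and almost no single gene of DNA replication or mitosis passed the test. Of 16 measured quiescence and FOXO target genes 5 fell and 1 rose (9 and 1 adjusted over the list alone). The insulin receptor substrate gene IRS2 fell (-0.93 ± 0.11), the growth arrest gene GAS1 (-0.78 ± 0.10), KLF9 (-0.59 ± 0.10) and CCNG2, an atypical cyclin, (-0.52 ± 0.12). The gene that rose was TXNIP (0.45 ± 0.11), a FOXO and glucose target named after its value was seen. The set was lower in camera (adjusted p = 0.000167, and adjusted p = 0.0976 with an estimated correlation). Of 29 measured DNA replication genes 1 rose, 0 fell and 28 did not pass (1 and 0 adjusted over the list alone), with a median of 0.13 and positive values in 26. The gene that rose was UHRF1, a chromatin factor of DNA replication (0.53 ± 0.11). Of 30 measured mitotic genes 0 passed in either direction, also adjusted over the list alone; the median was 0.15 and the largest value that of CDC20, 0.34 ± 0.12 (adjusted p = 0.151). Each of these 2 sets was higher in camera (adjusted p = 0.00167 and 0.00405), with adjusted p = 0.111 and 0.0982 with an estimated correlation. Of 19 measured ribosome biogenesis genes 3 rose and 0 fell (3 and 0 adjusted over the list alone): NOLC1 by 0.59 ± 0.11, NOP56 by 0.48 ± 0.10 and NOP2 by 0.42 ± 0.11. The ribosome biogenesis set was higher (adjusted p = 4.90e-05, and adjusted p = 0.0982 with an estimated correlation). With all 6 arrays unweighted the ribosome biogenesis set was also higher (adjusted p = 0.0116, and adjusted p = 0.988 with an estimated correlation), and the quiescence, replication and mitosis sets did not pass (adjusted p = 0.152, 0.152 and 0.292). UHRF1, KLF9, CCNG2, NOLC1, NOP56 and NOP2 lost their calls when either remaining unstimulated array was left out. Without PDGF-BB replicate 2, UHRF1, CCNG2, NOP56 and NOP2 lost theirs too, as did the last 3 without replicate 3 and NOP2 without replicate 1 (adjusted p up to 0.194). The other probe of NOP2 and 1 of the 2 others of CCNG2 had the opposite sign.

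**Figure D3:**
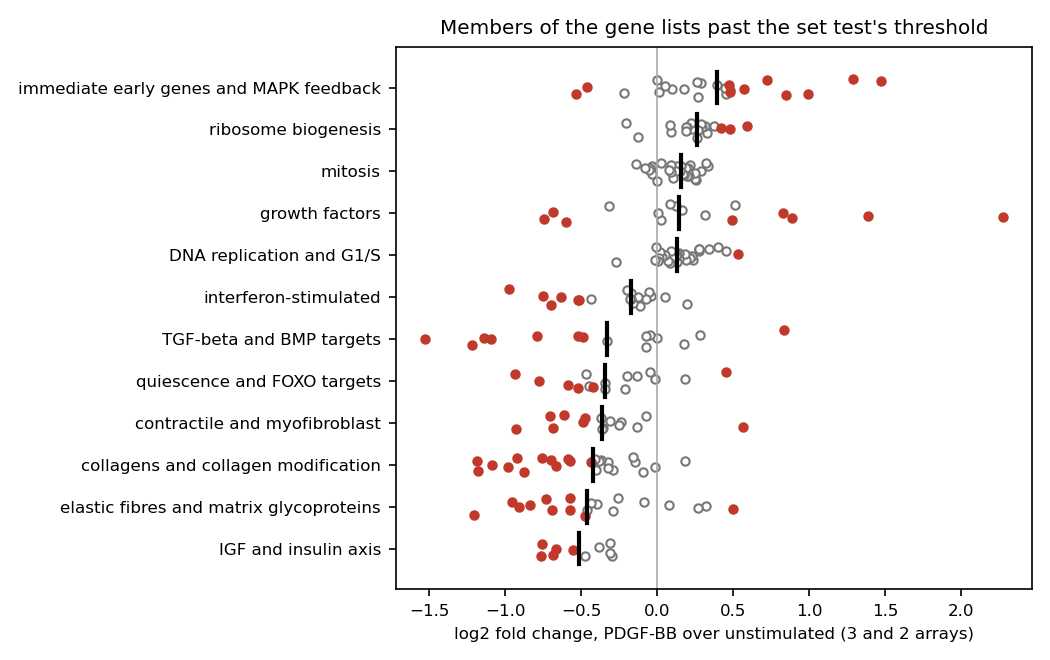
Log2 fold change (PDGF-BB over unstimulated, 3 and 2 arrays) of each measured member of the 12 gene lists past the threshold of camera with a preset correlation; filled points are genes with an adjusted p under 0.05, open points did not pass, and black lines are list medians. The collagen list has a median of -0.42 with 12 members past the threshold, and the mitosis list a median of 0.15 with 0.

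Interferon-stimulated genes fell in part. Of 19 measured genes 6 fell, 0 rose and 13 did not pass (7 fell adjusted over the list alone). The antiviral genes MX1 and MX2 fell (-0.97 ± 0.10 and -0.75 ± 0.12), OAS2 (-0.70 ± 0.13) and IFIT2 (-0.63 ± 0.12). The set was lower in camera (adjusted p = 0.000167, and adjusted p = 0.0976 with an estimated correlation), also with all 6 arrays unweighted (adjusted p = 0.0133, and adjusted p = 0.531 with an estimated correlation) but not there with median scaling, with no detection filter or without unstimulated replicate 2. In that fit of 6 arrays the list was lower only relative to the other genes: its median was 0.18, with 12 of 19 values positive. When 1 more unstimulated array was left out, MX2 (replicate 3), OAS2 and IFIT2 (replicate 2) lost their calls (adjusted p up to 0.130).

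Metabolic and stress lists held few changes. Of 18 measured sterol synthesis genes 1 fell, TM7SF2 (-0.89 ± 0.10), and of 13 fatty acid synthesis genes 1 rose, MID1IP1 (0.46 ± 0.11). Of 20 glycolysis genes HK2 rose (0.70 ± 0.12) and ALDOC fell (-0.74 ± 0.11). Of 18 genes of the amino acid and ATF4 response the serine synthesis gene PSAT1 fell (-0.57 ± 0.10), and of 14 chaperones of the endoplasmic reticulum SDF2L1 rose (0.47 ± 0.11). Of 17 lysosomal genes CTSF fell (-0.58 ± 0.11) and CTSA (-0.41 ± 0.10), and of 7 complement and apolipoprotein genes C1R fell (-0.76 ± 0.13) and C1S (-0.59 ± 0.11). Of 13 p53 targets 0 passed, and the largest change was -0.41 ± 0.13 for TP53INP1 (adjusted p = 0.110). None of these 8 lists shifted in camera. In fry p53 targets, sterol synthesis and complement were lower (adjusted p = 0.00546, 0.0120 and 0.0316) and chaperones higher (adjusted p = 0.0363). The lowest camera adjusted p was that of sterol synthesis, 0.0518, which with all 6 arrays unweighted was 0.0139 (adjusted p = 0.266 with an estimated correlation). That call was lost with median scaling, with no detection filter, with the stricter one and without unstimulated replicate 3. In the unweighted fit of 6 arrays the sterol list had a median of -0.06, with 7 of 18 values positive. Without the dim array the sterol list passed in 8 of the 16 other settings, among them no background correction, cyclic loess and the deposited normalized values. With an estimated correlation its camera adjusted p without the dim array was 0.190. Adjusted over the list alone, the counts were 0 higher and 1 lower for sterol synthesis, 1 and 0 for fatty acid synthesis, 2 and 1 for glycolysis and 1 and 4 for the ATF4 response. They were 3 and 0 for chaperones, 0 and 3 for lysosomal genes, 0 and 2 for complement and 0 and 0 for p53 targets. Leaving out 1 more array ended the calls of MID1IP1, HK2, PSAT1, SDF2L1, CTSF, CTSA, C1R and C1S (adjusted p up to 0.198).

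Most markers of endothelial, epithelial, melanocyte and blood cells were not detected. Of the listed genes with a probe, 1 of 11 endothelial, 1 of 7 melanocyte and Schwann cell, 2 of 11 leukocyte, 3 of 12 epithelial and 4 of 7 pericyte genes were detected on all 5 arrays, against 14 of 16 fibroblast genes. VIM, the most abundant fibroblast marker, had a value of 0.05 ± 0.10 (adjusted p = 0.837). Of the 14 measured fibroblast genes, COL1A1 and COL1A2 fell and the transcription factor gene PRRX1 (0.77 ± 0.11) and NT5E (0.57 ± 0.13) rose, 3 and 3 adjusted over the list alone. The most abundant markers of the other types did not pass: CD68 (0.22 ± 0.10), KRT10 (-0.01 ± 0.14), MITF (0.11 ± 0.17), PECAM1 (0.05 ± 0.12) and the pericyte gene CSPG4 (0.17 ± 0.11). The endothelial gene VWF had a value of -0.23 ± 0.12 and was detected on 1 of 3 stimulated arrays. The desmosome gene DSP fell (-0.60 ± 0.11) and the potassium channel gene KCNJ8, listed as a pericyte marker, (-0.60 ± 0.11). The fibroblast and pericyte lists did not shift as sets (camera adjusted p = 0.882 and 0.795), and with all 6 arrays unweighted the fibroblast list was lower (adjusted p = 0.0287, and adjusted p = 0.281 with an estimated correlation), a call that was lost in 8 of the other settings and turned to higher with median scaling. Its median there was 0.22, with 8 of 14 values positive, so it was lower only relative to the other genes. NT5E, DSP and KCNJ8 lost their calls when 1 more array was left out (adjusted p up to 0.171).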

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

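With all 6 arrays, every setting called 0 genes higher and 0 lower except cyclic loess (46 and 88, of which 18 and 17 by at least 2-fold), array quality weights (417 and 652, 30 and 37 by at least 2-fold) and the stricter detection filter (0 and 1, GAS6, by at least 2-fold). Leaving out each array in turn gave 0 to 258 higher and 0 to 475 lower, and 0 to 33 and 0 to 41 by at least 2-fold; each highest value is the one without unstimulated replicate 1. The value of PDGFRB with all 6 arrays, 0.27, reversed to -0.58 with array weights and to -0.57 without unstimulated replicate 1, ranging from -0.57 to 0.70 over the left-out arrays, and was -0.41 with cyclic loess; 8 more named genes that fell without the dim array had positive values with all 6 arrays. With all 6 arrays 10 gene lists passed camera, 6 with the stricter filter, 5 to 12 over the left-out arrays, and 0 with an estimated correlation or with fry. Under the stricter filter 1767 genes were tested, and only 6 of the 10 lists could be compared. Of these 5 were kept and sterol synthesis was lost, while mitosis was gained. Median scaling with all 6 arrays gave 8 lists, but kept only 2 of the 10, immediate early genes and ribosome biogenesis, with 7 lost, 5 others gained and fibroblast identity past the threshold in the opposite direction; the direction turned for collagens, contractile genes, matrix glycoproteins, fibroblast identity and sterol synthesis. The collagen median was then 0.35, against -0.25 in the fit fixed beforehand. Leaving out unstimulated replicate 2 or 3 from the 6 arrays lost the immediate early, matrix glycoprotein, ribosome biogenesis and fibroblast identity lists, the former also interferon-stimulated genes and the latter also sterol synthesis. The fibroblast identity call was lost as well with cyclic loess, no detection filter, array weights, the replicate block and without PDGF-BB replicate 1 or unstimulated replicate 1, and the interferon call with no detection filter. Without the dim array, settings combined after its signals were seen gave 258 genes higher and 475 lower as reference. The number higher was 451 with normal-exponential background and an offset of 50 (18 higher and 20 lower by at least 2-fold), 411 with the deposited normalized values and 435 with trend and robust eBayes. Leaving out 1 more array gave 97 to 182 higher and 187 to 364 lower. There 12 of the 26 lists tested passed camera, 0 passed with an estimated correlation and 18 of the 26 passed fry. The estimated correlation was below the preset 0.01 in the contractile (-0.0219), mitosis (-0.0301) and quiescence (-0.0501) lists, for example. It was above 0.01 in others, such as the collagen (0.0271) and IGF (0.140) lists. Where it was below, correlation between genes does not account for the higher p. The test with an estimated correlation takes its p from the residual degrees of freedom of the fit, 3 here, and the preset test does not. That alone raises p, so the higher p does not measure correlation in the lists above 0.01 either. The 20 NUP genes, with an estimated correlation of -0.0002, went from a camera p of 3.6e-05 to 0.0204. Growth factors were lost with no detection filter and with the stricter one, and sterol synthesis was gained in 8 of the 16 other settings (other backgrounds, cyclic loess, deposited normalized values, no filter, trend and robust eBayes, mean of probes, without unstimulated replicate 2). With the replicate block, 275 genes were higher and 494 lower without the dim array. The cause of these differences between settings was not tested, apart from the dim array weighed in the closing section.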

Other observations

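The symbol families, KLF genes, collagen tests and fibroblast-gene test of the dim array were chosen after related results had been seen, and the YAP and SRF lists after the fixed lists' results but before their own genes' values. Among 156 families of genes with a shared symbol stem, nucleoporins (20 NUP genes, median log2 fold change 0.21, camera adjusted p = 0.00561) and mitochondrial ribosomal proteins of the large subunit (48 MRPL genes, median 0.16, adjusted p = 0.00985) were higher after PDGF-BB, each with adjusted p = 0.998 with an estimated correlation. Of the members, 0 NUP genes and 1 MRPL gene passed the threshold. KLF4 (-1.19 ± 0.13) and KLF2 (-0.79 ± 0.10) fell together with KLF9, and the KLF family as a whole had an adjusted p of 0.108.

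The dim array could be a mislabelled culture, RNA of another cell type, or unstimulated RNA that gave little labelled target. The dim array was compared on the 307 probes past the threshold without it that were also detected on it. There its deviation from the other arrays correlated at -0.212 with the fold change (permutation p = 0.00022). That is the side of unstimulated cells, although only 53.4% of those probes lay on that side. The permutation treats the probes of this 1 array as independent, so its p does not measure how surely the culture was unstimulated. Over the 1000 brightest probes of the other arrays its rank correlation with the other unstimulated arrays was at least 0.869, below the 0.933 to 0.986 found among the other arrays. In a test that replaced an earlier one after its value was seen, the 6 fibroblast genes COL1A1, COL1A2, COL3A1, DCN, LUM and SPARC had a median percentile of 99.3 on that array. Among them SPARC was lowest at 93.8, against a mean of 97.2 on the other arrays. The pericyte gene RGS5 was detected on all 3 unstimulated arrays, the dim one among them, and on 2 of the 3 PDGF-BB arrays. The fibroblast gene PRRX1 was not detected on the dim array. That was the common case there, since 32.5% of the probes detected on each of the other 5 arrays were detected on it. In the fit of all 6 arrays, after quantile normalization, RGS5 had a mean of 6.31 and an SD of 2.73 on the unstimulated arrays. On the stimulated ones its mean was 4.57. Little target from unstimulated fibroblasts met its prediction, but the rank correlation in it cannot tell unstimulated from stimulated cells. The other arrays, of both groups, correlated highly with each other. The dim array was not compared with the PDGF-BB arrays in this way. Only the correlation of -0.212 bears on the treatment. Another or mixed source of the RNA is not excluded. Whether the loss arose in the RNA, the labelling or the hybridization is open.

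The fall of the collagen list could stem from a trend of the fold change with signal or from the choice of background and scaling. The median of 10000 random lists matched on signal was 0.01 (exactly 0.0081), against -0.42 for the collagens, and 0% of them were as low. The highest collagen median under the other backgrounds and scalings was -0.40 without the dim array, so neither reading accounts for the fall there. With all 6 arrays the median was -0.21 with an offset of 50 and 0.35 with median scaling, so in that fit the choice of scaling is not excluded, and a batch shared by the 2 usable unstimulated arrays was not tested.

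The fall of CCN2 and of contractile genes may reflect lower activity of YAP or of SRF with its MRTF cofactors, each of which drives such genes. Of 15 other YAP targets the median was -0.31 (95% bootstrap interval over genes -0.43 to -0.08, camera p = 0.0032, and p = 0.0514 with an estimated correlation). Past the threshold 2 of them fell, CRIM1 (-0.92) and AJUBA (-0.62), and 1 rose, FJX1 (0.93). Of 16 other SRF and MRTF targets the median was -0.14 (-0.20 to -0.02, camera p = 0.0385, and p = 0.220 with an estimated correlation), and LIMA1 (-0.62) fell. These intervals resample the genes of a single comparison and do not measure the spread between cultures. The YAP reading met its prediction, though not past 0.05 with an estimated correlation, and the SRF reading stayed undecided. Protein activity was not measured, so a shift of shared target genes by another route is open.

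The 10 possible splits of the arrays are too few for a share under 0.05. With all 6 arrays the real split gave 0 genes and the highest other 0, so all 10 reached it; for gene lists the real split gave 10 and the highest other 2, so 1 of 10 reached it. Without the dim array the real split gave 733 genes and the highest other 0, so 1 of 10 reached it, while in gene lists it gave 12 and the highest other 11. The other splits that kept both unstimulated arrays together, with 1 PDGF-BB array, gave 10 or 11 lists. Such splits still hold part of the treatment contrast, so they do not show what an arbitrary grouping gives. The splits that separated the unstimulated arrays gave 0 or 1 list.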
